A study of Mus musculus with 6 samples.

How the data were processed

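The 6 libraries were made from liver RNA of wild-type C57BL/6 mice, 3 given oil and 3 given CCl4. Per the labels' protocols, total RNA was isolated with a spin-column kit, 1.3 µg was used per library, and libraries were built with a SMARTER kit for messenger RNA. Per the series' design text, adapters, reads of low base quality and reads with many undetermined bases were removed, and the remaining reads were aligned to a reference genome with HISAT2. Per the submitters' processing notes, reads were then counted per gene with featureCounts. The versions, the genome build, the annotation, the strand setting and the treatment of reads that match several genes are not given in the sources used here. Reads of overlapping or antisense genes therefore cannot be told apart with certainty, and genes of families with near-identical copies (Mup, Cyp2, Saa, Orm, Gsta, Gstm, Ugt2b, Serpina and haemoglobin genes) have uncertain values of their own. Library preparation of this kind includes PCR, and no molecular identifiers are mentioned, so intervals from counts cover counting error only.

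The deposited values are raw counts per gene, whole numbers that sum to between 18929972 and 20042731 per library. The table has 55802 rows, of which 55359 carry Ensembl gene identifiers and 443 identifiers of another kind. Symbols were taken from the GENCODE M21 annotation by gene identifier, and 52083 of the 55359 identifiers matched. Some identifiers are newer than that annotation, and the build behind the counts is not given, so no coordinates are printed. The rows without an Ensembl identifier hold 0.543 to 0.679% of the counts per library. Of 269 of them tested, 58 were higher and 60 lower. No count was recorded in any library for 25777 rows.

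All columns were mapped to samples by their names. Replicates within a group were compared first. Their log CPM values correlated at 0.985 to 0.993, and every pair within a group differed by more than sampling noise (chi-square per gene of 5.71 to 25.8), so none was taken as a repeat of another. The highest values, 20.1 and 25.8, were those of the pairs with CCl4 replicate 3. The libraries held counts for 23351 ± 160 genes in controls and 24394 ± 278 in CCl4 livers, and the 10 most abundant genes took 16.4 ± 0.33% and 17.7 ± 0.11% of the counts.

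Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr (15579 genes, 308 of them without a symbol), libraries were scaled by TMM, and the group effect was tested with glmQLFit and glmQLFTest, with robust estimation and p-values adjusted by the Benjamini-Hochberg method. The common biological coefficient of variation was 10.63%. CPM values are relative to the TMM-scaled library size. Standard errors are the log2 fold change divided by the square root of F, and 95% intervals use the t quantile at the test's total degrees of freedom. Log2 fold changes are CCl4 over control.

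The 33 gene lists, the tests, the rule for named genes and the alternatives were fixed before the data were examined. Lists of at least 5 tested genes were tested with limma 3.58.1's camera at a preset correlation of 0.01. Beside it stand camera with an estimated correlation and fry, which asks if a list moves on balance in 1 direction and does not compare it with other genes. The rule for named genes took the 5 largest rises and the 5 largest falls with an adjusted p under 0.05, at least 10 CPM in the higher group, a symbol that is not a clone name, and no overlap of the groups. From the 8 called lists with the smallest p it took the called member of smallest adjusted p and the called member of highest mean CPM, and from other called lists the member of smallest adjusted p. Acta2, Col1a1, Timp1, Cyp2e1, Cyp7a1, Glul, Alb and Mki67 were named whatever their result. The rule named 41 genes. Besides those given above, they are Gpnmb, Akr1c18, Mmp12, Cyp2b9, Cyp2a4, Mup10, Cfd, Mup19, Hsd3b5, Mup15, Ctss, Lyz2, Ccnd1, Sparc, Col3a1, Lox, Plod1, Lgals1, Itgb5, Itih4, Hpx, Ugt2b1, Mgst1, Slco1a1, Anxa3, S100a8, Ppara, C1qc, Irf8, Eda2r, mt-Atp6, Mlxipl and Cyp2c38. All other genes were named after their values were seen, as examples of a list or because a count of 5 or fewer was given, and some genes are not reported here.

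The alternatives were other scalings (size factors of the DESeq2 kind, upper quartile, library size alone), no filter on low counts, and a stricter filter (10 counts in 3 libraries and a mean of 1 CPM). Others were DESeq2 1.42.0, limma-voom, a minimum fold change of 1.5 (glmTreat), the replicate number as a block, and each library left out in turn. Leaving out the 20 most abundant genes was added after seeing the data. The main test was checked on simulated counts for this comparison, drawn with the control means in both groups and the real library sizes. After the filter 15016 genes were tested. It recovered 73.1% of 93 genes changed by 1 on the log2 scale and 98.9% of 91 changed by 2, with 10 false calls among 14832 unchanged genes. The 95% intervals covered the true change in 90.3% and 91.2% of those genes. Few genes were changed there, with rises and falls planted in equal number. It therefore does not check the scaling or the false calls under a change as wide and uneven as that in the data. In the simulation camera called 1 of 1 changed list and 0 of 20 random ones. Genes were drawn independently there, so this does not test the preset correlation. At that setting camera called 10 to 19 lists in the splits of the real libraries that mix the groups. Those splits still hold part of the group difference.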

Results

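The libraries measured messenger RNA in the livers of wild-type C57BL/6 mice. Mice of the CCl4 group received carbon tetrachloride, a solvent that hepatocytes convert to a reactive radical and that is given to rodents to bring about liver injury and fibrosis. Control mice received oil. Each group held 3 libraries, and the labels give neither a dose nor a duration. The deposited table gives whole-number counts per gene, and the library totals ran from 18929972 to 20042731 counts. Per library, the totals were 19752831, 19370200 and 20042731 counts in the controls and 19292846, 19293751 and 18929972 in the CCl4 group. Nothing in the labels says that the libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may in part be technical.

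The comparison asked which liver transcripts differ after CCl4, in a series that its title presents as a model of liver fibrosis. In the CCl4 livers, 31 of 35 matrix protein genes, 24 of 25 macrophage and monocyte genes and 38 of 40 cell cycle genes were called higher. Col1a1 (ENSMUSG00000001506), which encodes a chain of type I collagen, stood at 11.6 ± 4.56 CPM (counts per 1000000, mean ± SD, n = 3) in controls and 165 ± 17.4 in CCl4 livers. Called lower were 18 of 32 genes of pericentral hepatocytes, 24 of 37 of phase II conjugation and 20 of 32 of bile acid synthesis and transport. Glul (ENSMUSG00000026473), the glutamine synthetase of the hepatocytes that line the central vein, went from 1257 ± 68.1 to 106 ± 17.6 CPM. Alb (ENSMUSG00000029368), which encodes serum albumin, stood at 71800.0 ± 3609 and 73971 ± 1664 CPM (log2 fold change 0.04, SE 0.07, adjusted p = 0.655). Alb was called higher when no scaling factors were used, at a log2 fold change of 0.19 and an adjusted p of 0.0446.

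Of 15579 genes tested with edgeR's quasi-likelihood test, 6427 (41.3%) passed a Benjamini-Hochberg adjusted p of 0.05. Of these, 3303 were higher and 3124 lower in the CCl4 livers. At a log2 fold change of at least 1 in size, 1568 were higher and 372 lower. The groups did not overlap in CPM for 8413 genes (54%), where chance gives 10%. Among the called genes, 3271 of the higher and 3087 of the lower ones had groups that did not overlap. The first principal component of log2 CPM held 77.2% of the variance and separated the groups. The second held 8.7% and set CCl4 replicate 3 apart from CCl4 replicates 1 and 2. The split of calls depended on the scaling. Upper quartile scaling gave 4103 higher and 2177 lower genes. Library size alone gave 4824 and 1676, and moved the median log2 fold change of all genes from 0.00056 to 0.147.

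**Figure D1:**
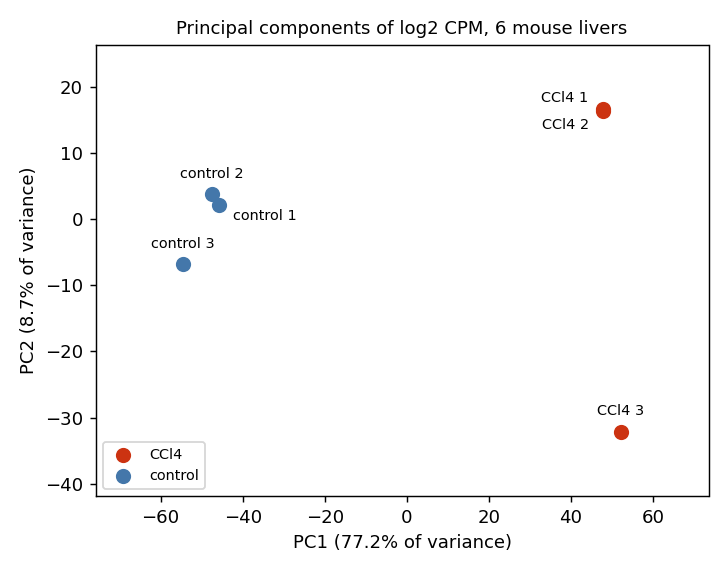
Principal components of log2 CPM, with the first component (77.2% of the variance) on the x axis and the second (8.7%) on the y axis; each point is a library, blue for control and red for CCl4. The 3 control libraries lie between -54.5 and -45.8 on the first component and the 3 CCl4 libraries between 47.8 and 52.2, and CCl4 replicate 3 lies at -32.1 on the second.

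In what follows, adjusted p-values of genes come from the edgeR test over all genes tested. Those of gene lists come from limma's camera with a preset correlation of 0.01, adjusted over 32 lists. Camera called 18 of the 32 lists, 11 higher and 7 lower, and with a correlation estimated from the data it called 0. With an estimated correlation the test also takes its degrees of freedom from the few libraries and not from the genes, so it has less power. The loss of all calls there cannot be put down to correlation alone. For bile acids the estimated correlation was 0.027, yet the adjusted p went from 9.31e-07 to 0.116. Under fry, which does not compare a list with other genes, 17 of these 18 lists kept their calls and lipogenesis did not. The correlations estimated for the called lists were above 0.01. They ran from 0.027 for bile acids to 0.746 for the acute phase. The list p-values at the preset correlation are therefore taken as too small. At that setting camera also called 10 to 19 lists in splits of the libraries that mix the groups, where part of the group difference remains. The number of members called was the same when p-values were adjusted over the list alone in 17 of 33 lists, and for the others both counts are given. Example genes beyond the rule for named genes were chosen after their values were seen.

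Of 35 fibrillar collagens and other matrix proteins, 31 were higher and 1 lower, with 33 higher and 1 lower when adjusted over the list alone. The median log2 fold change was 1.38 (adjusted p = 4.94e-30 for the list, and adjusted p = 0.116 with an estimated correlation). Col3a1, a fibrillar collagen, rose from 54.7 ± 12.2 to 391 ± 27.1 CPM (log2 fold change 2.84, SE 0.16, adjusted p = 2.89e-05). Col1a1 rose by 3.83 on the log2 scale (SE 0.29, adjusted p = 4.89e-04), Col1a2 by 3.24 and Sparc, a collagen-binding glycoprotein, by 1.94 (SE 0.06, adjusted p = 3.22e-07). Col5a3 was the member called lower (-0.38), and that call was lost with library size alone (adjusted p = 0.0559). Fn1, fibronectin, stood at 1717 ± 55 and 1688 ± 177 CPM, without a call (adjusted p = 0.841).

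Of 27 genes of matrix crosslinking and remodelling, 25 were higher and 0 lower, with a median of 1.83 (adjusted p = 1.43e-15, and adjusted p = 0.116 with an estimated correlation). The crosslinking enzyme Lox rose from 1.05 ± 0.336 to 8.77 ± 0.864 CPM (3.05, SE 0.21, adjusted p = 1.03e-05). Plod1, a collagen lysyl hydroxylase, rose by 0.25 (SE 0.05, adjusted p = 0.00451). Timp1 (ENSMUSG00000001131), an inhibitor of matrix metalloproteinases, rose from 0.232 ± 0.0842 to 2.64 ± 0.895 CPM (3.47, SE 0.41, adjusted p = 1.73e-04), and Mmp2 rose by 2.78.

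Of 24 markers of activated stellate cells and myofibroblasts, the matrix-producing cells of the liver, 17 were higher and 0 lower (median 1.00, adjusted p = 4.40e-11, and adjusted p = 0.123 with an estimated correlation). Lgals1 (1.72, SE 0.10, adjusted p = 3.91e-06) and Itgb5 (0.64, SE 0.08, adjusted p = 2.33e-04) were called, as were Vim (1.60), Pdgfrb (1.20) and Tgfb1 (0.98). Acta2 (ENSMUSG00000035783), the smooth muscle actin that marks myofibroblasts, stood at 3.91 ± 2.54 CPM in controls and 8.19 ± 1.53 in CCl4 livers, and was not called (1.07, SE 0.55, adjusted p = 0.189). Without control replicate 3, in which it stood at 1.01 CPM, Acta2 was called at 0.60 (adjusted p = 0.035). Of 21 markers of quiescent stellate cells, 6 were higher and 5 lower, with 6 higher and 6 lower when adjusted over the list alone (median 0.09, adjusted p = 0.856). The members called lower were Ecm1 (-1.18), Angptl6 (-1.08), Colec10 (-0.90), Pth1r (-0.74) and Vipr1 (-0.69).

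Macrophage and monocyte genes had the smallest list p-value. Of 25 members, 24 were higher and 0 lower, with a median of 1.92 (adjusted p = 4.61e-39, and adjusted p = 0.0558 with an estimated correlation). The protease Ctss rose from 31.9 ± 2.71 to 128 ± 8.85 CPM (2.00, SE 0.08, adjusted p = 6.38e-07) and lysozyme, Lyz2, from 69.5 ± 10.2 to 298 ± 26.0 (2.10, SE 0.12, adjusted p = 9.64e-06). Trem2, a lipid receptor of macrophages, rose from 0.639 ± 0.278 to 20.2 ± 1.33 CPM (4.96). Ccr2 (2.08), a receptor of recruited monocytes, Cx3cr1 (3.60), Lgals3 (3.36) and Spp1 (2.17) also rose. Of 17 Kupffer cell genes, which mark the resident macrophages, 9 were higher and 3 lower (median 0.87, adjusted p = 1.56e-04, and adjusted p = 0.343 with an estimated correlation). The complement gene C1qc rose by 1.33 (SE 0.09, adjusted p = 1.46e-05) and Vsig4 by 0.91. The members called lower were Timd4 (-0.97), C6 (-1.54) and Cd163 (-0.87). Clec4f, a marker of resident Kupffer cells, stood at 99.1 ± 8.89 and 102 ± 11.1 CPM (adjusted p = 0.760).

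Among the other immune lists, those of neutrophils and of dendritic cells were called. Of 11 neutrophil genes, 9 were higher and 0 lower (median 1.74, adjusted p = 1.20e-05, and adjusted p = 0.178 with an estimated correlation), among them the calcium-binding protein gene S100a8 (1.60 ± 0.104 to 5.42 ± 0.399 CPM, 1.75, SE 0.16, adjusted p = 4.66e-05). Lcn2, a member that hepatocytes also make in the acute phase, rose by 5.10. Of 15 dendritic cell and antigen presentation genes, 10 were higher and 0 lower, with 12 higher and 0 lower when adjusted over the list alone (median 0.72, adjusted p = 0.00111, and adjusted p = 0.310 with an estimated correlation). The transcription factor gene Irf8 rose by 1.23 (SE 0.09, adjusted p = 1.08e-05). Of 21 T, B and natural killer cell genes, 2 were higher, Cd8b1 (1.11) and Cd79a (0.59), and 0 lower. Adjusted over the list alone, 0 were called (list adjusted p = 0.905; median -0.01, mean 0.07). The call of Cd8b1 was lost without control replicate 1, control replicate 2 or CCl4 replicate 2 (adjusted p 0.0714 to 0.0788), and that of Cd79a without any one of the 6 libraries (0.056 to 0.0894). Of 18 chemokines and inflammatory cytokines, 8 were higher and 3 lower, with 9 higher and 3 lower when adjusted over the list alone (median 0.71, adjusted p = 0.0521). Ccl6 rose by 1.82, and those called lower were Cxcl13 (-2.09), Cxcl9 (-0.85) and Ccl24 (-0.79). Ccl24 lost its call without control replicate 1, control replicate 3, CCl4 replicate 1 or CCl4 replicate 2 (adjusted p 0.0668 to 0.0943). The chemokine list itself was called without control replicate 1 (adjusted p = 0.00609), CCl4 replicate 2 (0.0473) or CCl4 replicate 3 (0.0266). Of 30 interferon-stimulated genes, 7 were higher and 5 lower (adjusted p = 0.921; median -0.03, mean 0.04).

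Cell cycle genes had the highest median of the lists. Of 40 members, 38 were higher and 0 lower, with a median of 2.61 (adjusted p = 2.57e-30, and adjusted p = 0.262 with an estimated correlation). The proliferation marker Mki67 (ENSMUSG00000031004) rose from 4.62 ± 1.01 to 54.7 ± 19.3 CPM (3.57, SE 0.39, adjusted p = 0.00197). CCl4 replicate 3 lay below the other CCl4 libraries: the mean log2 CPM of the list was 3.71, 3.84 and 3.09 in CCl4 replicates 1, 2 and 3 (0.922 to 1.30 in controls), and Mki67 stood at 66.0, 65.7 and 32.4 CPM. Ccnd1, which encodes cyclin D1, rose from 18.3 ± 1.22 to 56.6 ± 6.00 (1.63, SE 0.09, adjusted p = 3.87e-06). The mitotic genes Cdc20 and Ccnb1 each rose by 4.79. Of 20 p53 targets, 11 were higher and 0 lower (median 0.28, adjusted p = 0.00549, and adjusted p = 0.310 with an estimated correlation). The receptor gene Eda2r rose from 0.554 ± 0.316 to 3.33 ± 0.616 CPM (2.58, SE 0.34, adjusted p = 3.22e-04), and Cdkn1a, a cell cycle inhibitor, rose by 2.48.

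**Figure D2:**
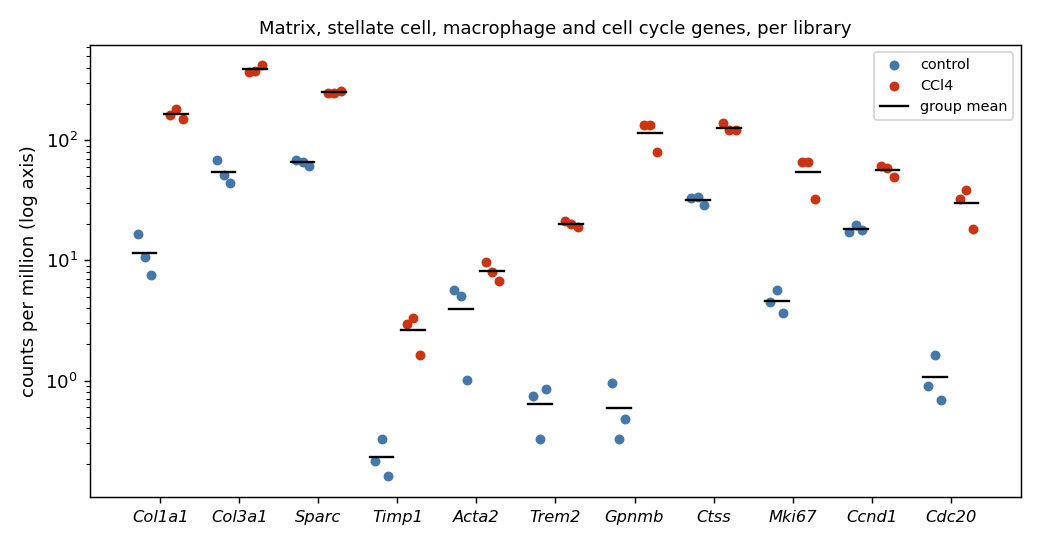
Expression in CPM (log y axis) of 11 genes of matrix, stellate cells, macrophages and the cell cycle; each point is a library, blue for control and red for CCl4 (n = 3 each), and the bars are group means. Col1a1 lies between 7.58 and 16.6 CPM in controls and between 150 and 184 in CCl4 livers, whereas the Acta2 libraries lie between 1.01 and 5.70 and between 6.73 and 9.78.

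Of 32 pericentral hepatocyte genes, 18 were lower and 4 higher, with 4 higher and 19 lower when adjusted over the list alone (median -0.65, adjusted p = 9.61e-09, and adjusted p = 0.269 with an estimated correlation). The log2 fold change of Glul was -3.57 (SE 0.12, adjusted p = 6.38e-07), which is 11.9-fold lower, with a 95% interval of 9.81 to 14.4. Cyp2e1 (ENSMUSG00000025479), the main enzyme that activates CCl4, went from 7206 ± 378 to 1995 ± 546 CPM (-1.85, SE 0.19, adjusted p = 3.94e-04). Oat, ornithine aminotransferase, changed by -4.58. The glutamate transporter gene Slc1a2 changed by -5.57, and by -6.65 without CCl4 replicate 3. The members called higher were Slc1a4 (1.97), Gstm3 (1.58), Cyp7a1 and Lect2 (0.43). Cyp7a1 (ENSMUSG00000028240), the rate-limiting enzyme of bile acid synthesis, went from 66.5 ± 34.2 to 242 ± 75.4 CPM (1.86, SE 0.46, adjusted p = 0.0338). Its call was lost without control replicate 1 (adjusted p = 0.0674), control replicate 3 (0.102), CCl4 replicate 1 (0.0701), CCl4 replicate 2 (0.0743) or CCl4 replicate 3 (0.0971). It was also lost with no filter on low counts (adjusted p = 0.0694). Of 29 periportal hepatocyte genes, 7 were higher and 10 lower, with 9 higher and 11 lower when adjusted over the list alone (adjusted p = 0.921; the median was 0.04 and the mean 0.01, against a downward test).

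Genes of drug metabolism changed in both directions. Of 42 cytochrome P450 genes of drug and steroid metabolism, 14 were higher and 18 lower (median -0.11, mean 0.06). The list was called lower (adjusted p = 0.0205, and adjusted p = 0.356 with an estimated correlation), and the call was lost without CCl4 replicate 2 (adjusted p = 0.0816) and in limma-voom (0.185). Cyp2c38 fell from 43.3 ± 4.72 to 3.05 ± 0.372 CPM (-3.83, SE 0.12, adjusted p = 2.62e-07). Cyp4a12a (-3.62), Cyp2a5 (-1.95) and Cyp1a2 (-0.67) were also lower, and Cyp2b10 (2.66) and Cyp2c55 (2.16) higher. Of 37 phase II conjugation genes, 24 were lower and 5 higher (median -0.45, adjusted p = 2.62e-08, and adjusted p = 0.123 with an estimated correlation). Ugt2b1, a glucuronosyltransferase, fell from 836 ± 20.7 to 293 ± 13.1 CPM (-1.51, SE 0.06, adjusted p = 8.31e-07), and Mgst1, a microsomal glutathione transferase, changed by -0.38 (SE 0.06, adjusted p = 9.96e-04). The higher members were Gsta1 (2.97), Gstm3, Gstm1 (0.43), Sult1d1 (0.39) and Tpmt (0.21). Tpmt lost its call without control replicate 2, control replicate 3, CCl4 replicate 1 or CCl4 replicate 2 (adjusted p 0.0716 to 0.125). Many genes of the Cyp2, Ugt2b, Gsta and Gstm families have close paralogs, and the treatment of reads that match several of them is not given in the sources used here, so their separate values are uncertain.

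Most of the genes called in the bile acid and lipid lists were lower. Of 32 genes of bile acid synthesis and transport, 20 were lower and 6 higher, with 6 higher and 21 lower when adjusted over the list alone (median -0.41, adjusted p = 9.31e-07, and adjusted p = 0.116 with an estimated correlation). The transporter gene Slco1a1 went from 631 ± 17.9 to 26.7 ± 5.09 CPM (-4.56, SE 0.14, adjusted p = 1.04e-06). Cyp7b1 (-3.23), Cyp8b1 (-1.71), Cyp27a1 (-1.0) and Scp2 (-0.93) were lower, and the efflux pump gene Abcc4 (2.03) was higher. Of 35 genes of fatty acid oxidation and ketogenesis, 18 were lower and 1 higher, with 1 higher and 19 lower when adjusted over the list alone (median -0.29, adjusted p = 2.85e-05, and adjusted p = 0.356 with an estimated correlation). Ppara, the nuclear receptor that drives this pathway, fell from 122 ± 9.74 to 50.3 ± 2.84 CPM (-1.27, SE 0.07, adjusted p = 3.91e-06). The higher member was Acot2 (1.15). Of 36 genes of lipogenesis and cholesterol synthesis, 10 were lower and 1 higher (median -0.20, adjusted p = 0.0101, and adjusted p = 0.843 with an estimated correlation). This call was lost without CCl4 replicate 1 (adjusted p = 0.0584) and under fry (0.206). The mean log2 CPM of the list was 7.37, 7.22 and 7.52 in control replicates 1, 2 and 3 and 6.75, 7.02 and 7.46 in the CCl4 ones, so that CCl4 replicate 3 lay within the control range. The transcription factor gene Mlxipl changed by -0.83 (SE 0.07, adjusted p = 2.06e-05), while Scd1 stood at 8144 ± 1723 and 8058 ± 1774 CPM (adjusted p = 0.962). Of 36 genes of gluconeogenesis, glycolysis and amino acid catabolism, 8 were higher and 11 lower, with 8 higher and 12 lower when adjusted over the list alone (adjusted p = 0.825; the median was 0.04 and the mean 0.04, against a downward test). Of 13 mitochondrially encoded genes, 10 were lower and 0 higher, with 0 higher and 11 lower when adjusted over the list alone (median -0.31, adjusted p = 0.00700, and adjusted p = 0.572 with an estimated correlation). Their counts made up 5.53 ± 0.04% of control and 4.88 ± 0.17% of CCl4 libraries, and mt-Atp6 changed by -0.41 (SE 0.08, adjusted p = 0.00224).

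**Figure D3:**
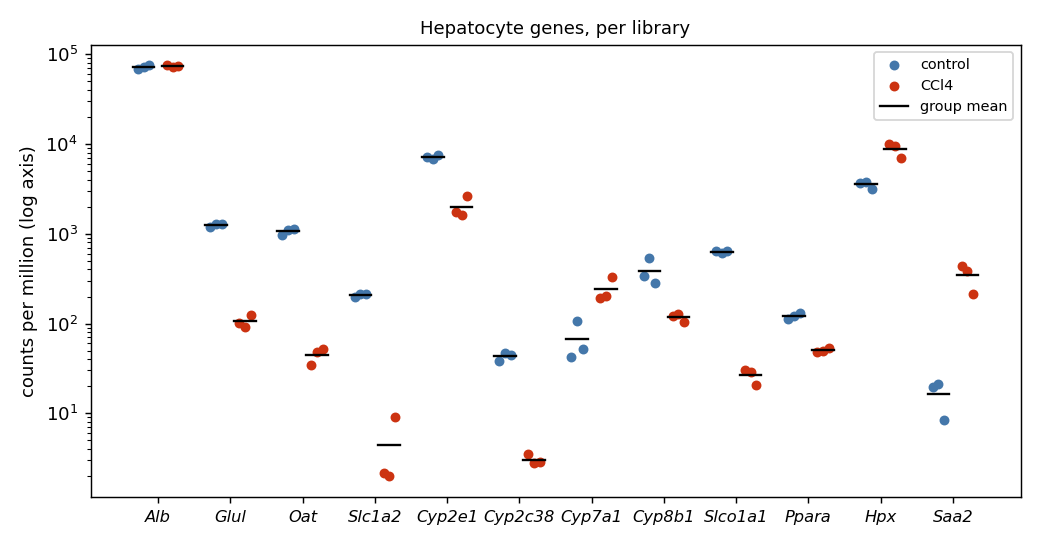
Expression in CPM (log y axis) of 12 genes that hepatocytes express; each point is a library, blue for control and red for CCl4 (n = 3 each), and the bars are group means. The Glul libraries lie between 1178 and 1298 CPM in controls and between 91.8 and 126 in CCl4 livers, while the Alb libraries of both groups lie between 68448 and 75630.

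Of 23 acute phase genes, 17 were higher and 1 lower, with 18 higher and 1 lower when adjusted over the list alone (median 1.22, adjusted p = 1.96e-09, and adjusted p = 0.356 with an estimated correlation). Hpx, which encodes the haem-binding protein hemopexin, rose from 3551 ± 344 to 8869.6 ± 1704 CPM (1.32, SE 0.15, adjusted p = 3.85e-04), and Itih4 rose by 1.01 (SE 0.10, adjusted p = 6.46e-05). The mean log2 CPM of the list was 8.58, 8.45 and 7.92 in CCl4 replicates 1, 2 and 3, and 6.57 to 6.98 in controls. Saa2 (4.39) and Orm2 (4.13), which have near-identical paralogs, were called higher. The lower member was Crp (-0.28). Its call was lost without control replicate 1, 2 or 3 or CCl4 replicate 2 or 3 (adjusted p 0.0511 to 0.13), and with upper quartile scaling (0.136) or library size alone (0.234). Of 30 secreted proteins of hepatocytes, 6 were higher and 10 lower (median -0.13, adjusted p = 0.233), among them Serpina3k at -1.23. Of 23 NRF2 and oxidative stress genes, 10 were higher and 6 lower, with 11 higher and 6 lower when adjusted over the list alone (median 0.16, adjusted p = 0.0952). The metallothionein gene Mt1 (4.47) and the quinone reductase gene Nqo1 (1.23) were higher, and Gclc, of glutathione synthesis, was lower (-0.71). Of 22 genes of the unfolded protein response, 1 was higher, Atf3 (1.90), and 4 were lower, namely Herpud1 (-0.78), Xbp1 (-0.39), Trib3 (-0.76) and Atf4 (-0.23). The list was not called (adjusted p = 0.921; the median was 0.10 and the mean 0.17, against a downward test). Trib3 lost its call without control replicate 2, control replicate 3 or CCl4 replicate 2 (adjusted p 0.0517 to 0.0575). Atf4 lost its call without control replicate 1, control replicate 3, CCl4 replicate 1 or CCl4 replicate 2 (0.0634 to 0.0914), and with library size alone (0.415).

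Of 20 cholangiocyte and ductular genes, 13 were higher and 0 lower, with 14 higher and 0 lower when adjusted over the list alone (median 1.25, adjusted p = 3.43e-06, and adjusted p = 0.269 with an estimated correlation). Anxa3 rose from 6.93 ± 1.28 to 22.0 ± 2.58 CPM (1.67, SE 0.14, adjusted p = 3.51e-05), the progenitor marker Prom1 rose by 2.66 and Krt19 by 1.10. Of 21 sinusoidal endothelial genes, 6 were higher and 3 lower (adjusted p = 0.825; the median was -0.04 and the mean 0.13). Cd34, a marker of capillary endothelium, rose by 1.66. The lower members were Fcna (-0.67), Dnase1l3 (-0.32) and Kdr (-0.18), and Stab2 stood at 70.5 ± 1.98 and 67.1 ± 3.11 CPM (adjusted p = 0.334). Kdr lost its call without control replicate 1, control replicate 2, CCl4 replicate 2 or CCl4 replicate 3 (adjusted p 0.09 to 0.116), and with upper quartile scaling (0.255) or library size alone (0.639).

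Lists of other tissues and of handling were not called. Of 11 genes of adipocytes and mesothelium, 4 were higher and 4 lower, with 5 higher and 5 lower when adjusted over the list alone (median -0.42, adjusted p = 0.825). The mesothelial genes Wt1 (3.08), Upk1b (2.47), Lrrn4 (2.33) and Msln (2.13) were higher, and Car3 (-1.25), Plin4 (-1.29), Adrb3 (-0.83) and Cfd lower. The list joins 2 tissues, and its called mesothelial members rose while its other called members fell. A test for 1 direction therefore cannot speak for either tissue. Plin4 lost its call with no filter on low counts (adjusted p = 0.0531). Upk1b and Lrrn4 lost their calls without any one of the control replicates (adjusted p 0.0561 to 0.0744), as did Msln, which also lost its call without CCl4 replicate 1 or 2 (0.0627 to 0.141). Without CCl4 replicate 2, Upk1b stood at 1.75 and Lrrn4 at 1.58. All 3 also lost their calls with no filter on low counts (0.101 to 0.141) and in limma-voom (0.0655 to 0.162). Without control replicate 2 this list was called lower (adjusted p = 0.00102), the red blood cell list higher (0.00786) and the circadian clock list lower (0.0254). Of 9 red blood cell genes, 6 were higher and 2, Alas2 (-0.90) and Car1 (-1.05), lower (median 1.02, adjusted p = 0.696). Of 19 immediate early genes, which respond to handling, 3 were higher and 6 lower, with 4 higher and 6 lower when adjusted over the list alone (median -0.23, adjusted p = 0.571). The higher ones were Atf3, Egr2 (1.56) and Ier3 (1.03). Egr2 lost its call without control replicate 2, control replicate 3, CCl4 replicate 1 or CCl4 replicate 2 (adjusted p 0.0558 to 0.107) and stood at 2.20 without control replicate 1, and Ier3 lost its call without control replicate 1 (0.0513). Of 19 circadian clock genes, 1 was higher, Usp2 (1.16), and 5 lower, namely Nr1d1 (-1.34), Nr1d2 (-0.78), Cry2 (-0.61), Clock (-0.45) and Hlf (-0.43) (median -0.07, adjusted p = 0.136). Usp2 lost its call without control replicate 1 (0.0526), and Nr1d2 without control replicate 1, CCl4 replicate 1 or CCl4 replicate 2 (0.0541 to 0.0766). The interferon-stimulated genes called lower were Ifit3b (-0.61), Ifit1 (-0.51), Iigp1 (-0.47), Cmpk2 (-0.36) and Ifih1 (-0.28). With library size alone, Ifit3b, Ifit1, Cmpk2 and Ifih1 lost their calls (0.069 to 0.162). Ifit3b, Ifit1 and Cmpk2 also lost them without control replicate 1, control replicate 2 or CCl4 replicate 1, as did Cmpk2 without CCl4 replicate 2 and Ifit3b without CCl4 replicate 3 (0.054 to 0.143). Of the pancreas list, 1 gene was tested, Cela1, and it was lower (-1.39), with no list test.

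**Figure D4:**
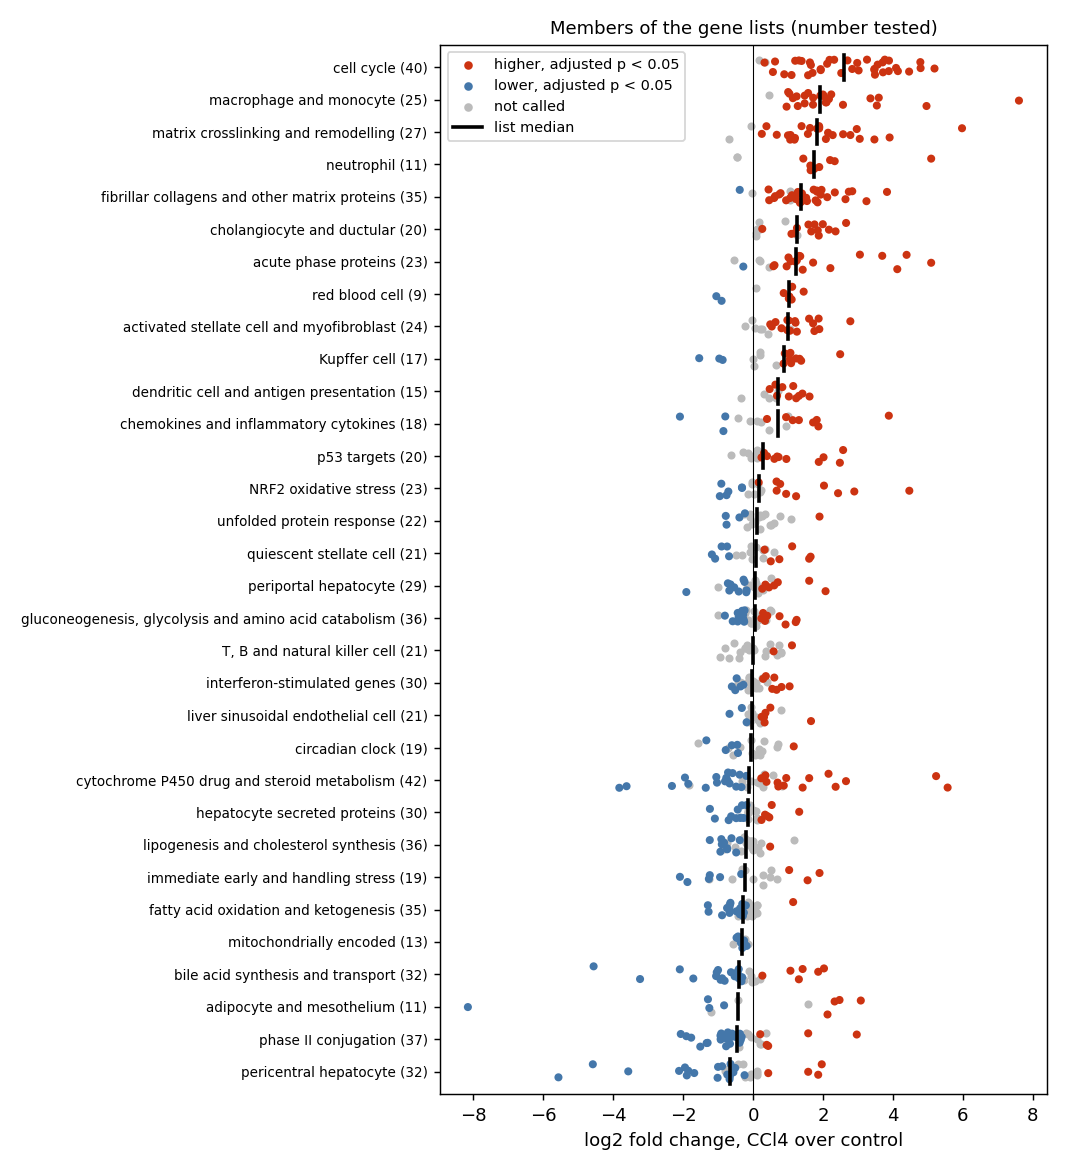
Log2 fold change, CCl4 over control (x axis), of the tested members of each gene list with at least 5 tested genes (y axis, with the number tested); each point is a gene, red if called higher, blue if called lower and grey if not called, and black bars are list medians. The medians drawn run from -0.65 in pericentral hepatocyte genes to 2.61 in cell cycle genes.

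The 5 largest rises that met the rule were of Gpnmb, Akr1c18, Mmp12, Cyp2b9 and Cyp2a4. Gpnmb (ENSMUSG00000029816), a membrane glycoprotein of lipid-laden macrophages, rose from 0.587 ± 0.331 to 116 ± 31.5 CPM (7.61, SE 0.43, adjusted p = 1.83e-04), which is 195-fold with a 95% interval of 90.9 to 418. Akr1c18 (ENSMUSG00000021214), a steroid dehydrogenase, rose from 0.142 ± 0.0605 to 14.4 ± 2.84 CPM (6.60, SE 0.28, adjusted p = 1.04e-06). Mmp12 (ENSMUSG00000049723), the macrophage elastase, rose from 0.604 ± 0.344 to 38.6 ± 18.3 CPM (5.98, SE 0.73, adjusted p = 0.00331), a call that limma-voom did not make (adjusted p = 0.0621). Cyp2b9 (ENSMUSG00000040660) rose by 5.57 (SE 0.60, adjusted p = 0.00237) and Cyp2a4 (ENSMUSG00000074254) by 5.24 (SE 0.48, adjusted p = 0.00114). Both have close paralogs, Cyp2b10 and Cyp2a5, so their separate values are uncertain.

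The 5 largest falls were of Mup10, Cfd, Mup19, Hsd3b5 and Mup15. Hsd3b5 (ENSMUSG00000038092), a steroid dehydrogenase of male liver, fell from 285 ± 17.6 to 1.32 ± 0.592 CPM (-7.74, SE 0.21, adjusted p = 2.22e-06). Mup15 (ENSMUSG00000096674), a major urinary protein gene, fell from 492 ± 45.2 to 2.72 ± 1.32 CPM (-7.50, SE 0.31, adjusted p = 3.80e-05). Mup10 (ENSMUSG00000078680) stood at 393, 837 and 18.3 CPM in the controls and 1.03 ± 0.640 in CCl4 livers (-8.65, SE 2.04, adjusted p = 0.0319). Mup19 (ENSMUSG00000078673) stood at 55.4 ± 47.1 and 0.216 ± 0.106 CPM (-7.97, SE 1.61, adjusted p = 0.0200). Cfd (ENSMUSG00000061780), which encodes the adipocyte protein adipsin, had 636 counts in the controls and 2 in the CCl4 group (adjusted p = 0.0270). It stood at 11.9, 1.51 and 20.4 CPM in control replicates 1, 2 and 3. The pooled counts gave a ratio of 342 after scaling for depth, with an interval of 94.3 to 2831 for counting error only. That interval leaves out the spread between libraries. The edgeR fit, which includes that spread, gave a 285-fold fall with an interval of 8.87 to 9180. Without control replicate 1 the adjusted p was 0.0708 for Mup10 and 0.0513 for Cfd, and without control replicate 2 it was 0.0704 for Mup10, at -7.64, and 0.0531 for Mup19. Without CCl4 replicate 1 it was 0.109 for Mup10, 0.0963 for Cfd and 0.0801 for Mup19, and without CCl4 replicate 2 it was 0.108, 0.172 and 0.0804. Without CCl4 replicate 3 it was 0.112, 0.117 and 0.0858. The log2 fold change of Mup19 was -7.13 without control replicate 1, and that of Cfd was -7.42 without control replicate 3 and -10.77 without CCl4 replicate 2. The CCl4 libraries left in that last fit held 0 counts of Cfd, so the size of its fall there is not measured. The calls of all 3 were also lost in limma-voom (0.174 to 0.378). Over the whole Mup family, which shares reads among near-identical copies, the share of counts was 2.54 ± 0.25% in controls and 0.387 ± 0.121% in CCl4 livers.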

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

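Leaving out the 20 most abundant genes was chosen after seeing the data. The other settings were chosen beforehand. The count of lower genes was 1676 with library size alone. With a minimum fold change of 1.5 the counts were 1309 higher and 380 lower, since that test asks for a larger change. Under the other settings both counts stayed within 1.5 times the main ones. Leaving out single libraries gave 2706 to 3305 higher and 2443 to 3103 lower genes, DESeq2 gave 2813 and 2534, and leaving out the 20 most abundant genes 3295 and 3120. The same replicate numbers occur in both groups. Deviations from the group means of libraries with the same number correlated at 0.048, 0.004 and 0.063, none above 0.1, so the numbers were not taken as pairs, and not every library correlated best with that of its own number. With the number as a replicate block, 6416 genes were called, 3298 higher and 3118 lower, 6056 of them also called without it, and the unfolded protein response list turned direction without a call (0.810). Under the block the P450 list was not called (0.128) and the chemokine list was (0.0428). Cyp7a1 was not called (adjusted p = 0.0893), nor were Hbb-bs (0.0644), Hba-a1 (0.0847), Cyp2c29 (0.0949), Epcam (0.0661) and Cd79a (0.0573).

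Of the 39 genes called under the rule, 34 kept their calls in each of 15 other settings (14 for Hpx, which was among the 20 most abundant genes). Mmp12, Mup10, Cfd, Mup19 and Cyp7a1 did not. The test against a minimum fold change is not among these settings, as calls of single genes were not followed there. Plod1, Mgst1 and mt-Atp6 changed by less than that minimum. Of 18 called lists, 16 kept their calls in all 14 other settings of camera with the preset correlation. With an estimated correlation the adjusted p was 0.0558 for macrophages, 0.116 for matrix proteins, crosslinking and bile acids, 0.123 for activated stellate cells and phase II, 0.178 for neutrophils and 0.262 for the cell cycle. It was 0.269 for cholangiocytes and pericentral genes, 0.310 for dendritic cells and p53 targets, 0.343 for Kupffer cells and 0.356 for acute phase, P450 and fatty acid oxidation. It was 0.572 for mitochondrial genes and 0.843 for lipogenesis. The P450 list was also lost in limma-voom (0.185) and without CCl4 replicate 2 (0.0816), and lipogenesis under fry (0.206) and without CCl4 replicate 1 (0.0584). Lists gained were chemokines with no filter (0.0217), under fry (0.0172) and in 3 of 6 fits with a library left out (0.00609 to 0.0707 over the 6), secreted proteins with no filter (0.0410), and NRF2 with no filter (0.0298) and under fry (0.00377). Without control replicate 2, the adipocyte (0.00102), red blood cell (0.00786) and clock (0.0254) lists were called. With libraries left out the adjusted p ran from 0.0145 to 0.0816 for P450, 9.45e-08 to 0.0584 for lipogenesis, 0.00102 to 0.981 for the adipocyte list, 0.00786 to 0.853 for red blood cells and 0.0254 to 0.225 for the clock.

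Other calls of single genes were lost by setting as follows. With no filter on low counts they were Mup10 (0.0540), Cfd (0.0557), Idi1 (0.0756), Nr1d2 (0.0823), Egr1 (0.0831), Cd79a (0.0897), Cyp2c29 (0.121) and Epcam (0.124). In DESeq2 they were Cmpk2 (0.0692), Ifit3b (0.0758), Tpmt (0.0936), Ccl24 (0.101), Cd8b1 (0.114), Kdr (0.125) and Cd79a (0.151). With upper quartile scaling they were Egr1 (0.0517), Ifit3b (0.0687), Cmpk2 (0.0737) and Atf4 (0.115), and with library size alone Egr1 (0.0519), Idi1 (0.0579) and Ccl24 (0.0586). The stricter filter lost Crp (0.0503) and Kdr (0.0514), and limma-voom lost Epcam (0.0527).

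No list that turned direction was called in that setting. They were periportal genes with upper quartile scaling (0.987), library size alone (0.957) and fry (0.770), interferon-stimulated genes with no filter (0.994) and with libraries left out (0.518 to 0.906), and T, B and natural killer cells with the stricter filter (0.973), limma-voom (0.996), fry (0.983) and without CCl4 replicate 2 (0.954; 0.651 to 0.981 with libraries left out). The unfolded protein response turned in limma-voom (0.932), fry (0.938) and with libraries left out (0.462 to 0.930 over the 6), and the adipocyte list with libraries left out. Genes without a call also turned. Fn1, Stab2 and Scd1 stood at 0.063, 0.015 and 0.073 with upper quartile scaling and at 0.12, 0.076 and 0.14 with library size alone. With libraries left out, Fn1 ran from -0.093 to 0.053, Scd1 from -0.18 to 0.14, Socs2 from -1.35 to 0.11, Cish from -0.92 to 0.20 and Clec4f from -0.035 to 0.12, and in limma-voom Cish stood at 0.17. The cause was not tested. At 18929972 to 20042731 counts per library, counting alone left the ratio of Cfd, which had 2 counts in the CCl4 group, between 94.3 and 2831. With the spread between libraries included, the edgeR fit left it between 8.87 and 9180.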

Other observations

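Genes that differ between male and female mouse liver were set against the comparison after the data had been seen, in lists written from background knowledge. Some members were among the largest changes already seen, so the p-values of these lists in part restate what had been seen. The p-values of these lists are also unadjusted, so they cannot be set beside the adjusted ones of the lists fixed beforehand. Of 39 male-biased genes tested, 36 were lower in the CCl4 livers and 0 higher, with a median log2 fold change of -2.49 (camera p = 8.62e-64, and p = 0.00545 with an estimated correlation). Elovl3, a fatty acid elongase, went from 572 ± 22.8 to 7.45 ± 3.05 CPM (-6.26, SE 0.31, adjusted p = 8.17e-05). Mup7 (-5.50) and Mup17 (-5.31), major urinary protein genes whose reads are shared with copies, and Cyp4a12a also fell. Of 32 female-biased genes tested, 15 were higher and 2 lower, with a median of 1.26 (camera p = 2.88e-05, and p = 0.172 with an estimated correlation). Cyp2b9, Cyp2a4 and Akr1c18 belong to this list. CCl4 replicate 3 stood apart in both lists: the mean log2 CPM in CCl4 replicates 1, 2 and 3 was 3.75, 3.68 and 4.57 for female-biased genes (2.75 to 2.88 in controls) and 4.89, 5.10 and 4.27 for male-biased ones (8.005 to 8.448). Of the members, 14 male-biased and 12 female-biased genes also stand in lists fixed beforehand.

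The tests of patterns that follow were chosen after the result was seen, except the test of the growth hormone targets Socs2 and Cish and the counts over other splits. For the sex-biased genes, female livers among the CCl4 libraries are argued against by Y-linked transcripts. Their summed CPM in the lowest CCl4 library was 0.863 of the control mean, and Xist stood at 0.151 to 0.295 CPM in CCl4 and 1.64 to 1.97 in control livers. A lower share of hepatocytes would lower their secreted proteins with the male-biased genes, but the difference between these lists in mean log2 CPM changed by -3.37 (SE 0.221, n = 3 per group), and without the Mup genes the male-biased median was -2.02, which shared Mup reads do not account for. A weaker response to growth hormone, a hormone that helps to set these genes apart by sex, may be a biological explanation and stays open. By the rule set beforehand, the lack of a call lower for both Socs2 and Cish was to count against it. Of Socs2 and Cish, 0 were called lower. Yet their 95% intervals, -2.29 to 1.78 and -2.95 to 2.16, hold falls as well as rises, so that rule could not decide. With libraries left out Socs2 ran from -1.35 to 0.11 and Cish from -0.92 to 0.20. The receptor Ghr (-0.95) and the transcription factor Stat5b (-0.55) were called lower.

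For the higher macrophage, matrix and cell cycle genes, a lower share of hepatocytes would raise the markers of other cell types alike. The macrophage minus sinusoidal endothelial mean log2 CPM rose by 2.04 (SE 0.058, n = 3 per group), which argues against that as the whole cause of the macrophage rise. The matrix and cell cycle lists were not set against endothelial genes in this way. More blood in the CCl4 livers would bring haemoglobin transcripts, the most abundant ones of blood, ahead of those of monocytes. Haemoglobin genes such as Hbb-bs (49.7 ± 19.8 to 107 ± 6.25 CPM) and Hba-a1 (26.0 ± 10.8 to 56.4 ± 4.42) were called higher, calls lost without control replicate 1 or any one of the CCl4 replicates (adjusted p 0.0929 to 0.136) and with no filter on low counts (0.0960 and 0.104), but the summed CPM of the macrophage list rose by 979 (SE 17.1) more than that of the 4 haemoglobin genes, which argues against blood as the whole source. In mean log2 CPM the macrophage list rose by 1.01 more than those genes (SE 0.348, under 3 times its SE), and blood as a part of the rise was not tested.

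For the lower pericentral genes, a lower share of hepatocytes would move pericentral and periportal genes alike, but their difference in mean log2 CPM changed by -0.837 (SE 0.130, n = 3 per group). A loss of pericentral cells stays open. It was taken to raise no member, but a member could also rise in the cells that remain, so higher members cannot decide this. Of the members, 1, Slc1a4, was called higher by at least 1 and kept that call with each library left out. Gstm3, Cyp7a1 and Lect2 were also called higher. Gstm3 has close paralogs, Cyp7a1 lost its call with libraries left out (adjusted p up to 0.102), and Lect2 rose by 0.43, which is less than 1. A change of expression within the remaining hepatocytes was not tested.

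The 6 libraries can be split in 10 ways into groups of 3, too few for a share under 0.05. The real split gave 3303 higher and 3124 lower genes, 1568 and 372 of them at a log2 fold change of at least 1, and the highest of the other splits gave 0. At an unadjusted p under 0.05, edgeR found 0.6 to 2.3% of genes in the other splits and 49.5% in the real one. Every other split holds both conditions on each side, which raises the spread within the sides. Low numbers of genes were therefore likely there and do not measure chance. For the gene lists the real split called 18 and the highest other split 19, and 4 splits, the real one included, called 18 or more. In those splits the libraries of both conditions are mixed, and camera with a preset correlation still called lists. The mixing is uneven, so a part of the difference between conditions stays between the sides. List calls there are therefore not a count of false ones.

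Some other values stood out. Of the P450 genes, Cyp2c29 was called higher (3227 ± 135 to 5936 ± 1886 CPM, adjusted p = 0.0318), although that call was lost without any one of the control replicates or CCl4 replicate 2 (0.0773 to 0.0826). The epithelial marker Epcam was called higher (1.58, adjusted p = 0.0253), a call lost without any one of the control replicates (0.0524 to 0.0865). The cholesterol synthesis gene Idi1 was called lower (-1.24, adjusted p = 0.0339), a call lost without any one of the control replicates or CCl4 replicate 2 (0.0751 to 0.0975). The immediate early gene Egr1 was called lower (-2.09, adjusted p = 0.0460), a call lost in 5 of 6 fits with a library left out, control replicate 3 being the exception (0.0691 to 0.122).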
